A study of Phaeodactylum tricornutum with 104 samples.

How the data were processed

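Strand-specific RNA-seq libraries of the marine diatom Phaeodactylum tricornutum were examined. Per the labels' protocols, cultures grew in K medium on an artificial seawater base with silicic acid added, under continuous light of 325 ± 25 µmol photons. RNA was extracted with Tri-Reagent, rRNA was removed with RiboZero, and directional libraries were made with a NEBNext Ultra kit. Per the series design, 4 cultures kept at 20 °C were each divided into a control flask at 20 °C and a heated flask at 28 °C, and the 8 flasks were sampled hourly. The labels hold 13 points per flask, from 0 to 12 h, where the design text gives 12. The labels of 2 libraries disagree: by title they are hours 11 and 12 of heated culture 2, and by characteristics they belong to the control arm and culture 3. Both were taken by title, because the titles fill every combination of arm, culture and hour exactly once.

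The deposited files hold raw read counts per gene, 1 file per library, with 10395 genes and 5 closing counts of reads given to no gene, in the layout of htseq-count. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.2 and Bowtie2 2.3.4.1 and handled with Picard and HTSeq. The versions of Picard and HTSeq, the genome build and the strand setting of the counting are not given in the sources used here. All 10395 gene identifiers matched the reference gene table of assembly ASM15095v2, which holds 10398 genes. That table was used only for names and for which genes lie next to each other. It names 724 genes by a symbol and gives no descriptions, so gene lists were matched on symbols alone.

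CPM values, counts scaled by each library's reads assigned to genes, were computed. For the main comparison the counts of hours 1 to 12 were summed per flask, since hourly samples of a flask are not replicates, and the CPM of these sums were scaled with TMM factors. CPM at single hours were not scaled further, except in the plots by hour and where they are named TMM-scaled. Differences between arms were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and the filterByExpr filter (minimum count 10). P-values were adjusted by the Benjamini-Hochberg method, and a gene is described as called where the adjusted p lay under 0.05. The same test was run at each hour on 4 heated against 4 control libraries. A further test compared the heat effect of hours 9 to 12 with that of hours 1 to 4, on sums per flask and period, and the same periods were compared within the control flasks. Every p-value is two-sided except the permutation p for adjacent genes, which is one-sided. Every adjusted p in the report is from edgeR unless another tool is named.

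Gene lists were tested with camera (limma 3.58.1) at its preset correlation, with an estimated correlation, and with fry, adjusted over the lists. Of 35 lists fixed as patterns on gene names, 16 matched at least 1 symbol and 19 matched none, which were left out. A further 17 lists were made from the symbols after the gene table was seen and before any test was run. Genes named in the report were chosen by a rule. For the summed comparison it took the 10 genes with a symbol and the largest change in each direction, among called genes with the same direction in all 4 culture pairs and a mean of at least 10 CPM. It added up to 2 called genes per fixed list, or all members of a list of 4 or fewer genes with a called member, and 2 genes without a symbol per direction. At hours 1 and 12 it took 5 genes per direction under the same conditions. For the comparison of periods it took up to 5 genes per direction without the condition on culture pairs. The onset of a gene is the first hour from which it was called in the same direction at 2 or more consecutive hours.

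The designs, the fixed lists, the naming rule and most alternatives were set before the data were examined. These alternatives were other size factors (RLE), no low-count filter, the Wald test of DESeq2 1.42.0, limma-trend on mean log2 CPM, 1 fit of all libraries, leaving out each flask or library, leaving out the libraries with conflicting labels, only libraries of the first plate, and the culture number as a replicate block. Alternatives on library sets (groups of file numbers that stood apart in the counts) and without hour 3 or hours 10 to 12 were chosen after seeing the data. The pairing of flasks by culture comes from the series design. In the sums, deviations of same-numbered flasks from their group means correlated across genes at 0.423 to 0.612, and at single hours from -0.71 to 0.747. By rule the fit without the block was the main one. In the comparison of periods the block was the flask, not the culture number.

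The tests of the summed hours, of hour 1 and of the periods were tested on simulated data with 200 changed genes and the real means and depths, and the other hours and the control flasks alone were not. The simulated counts varied independently, without effects of culture or library set shared across genes. The rates below therefore may not hold for the real data, where such effects were present. In the summed comparison (9680 genes) edgeR recovered 12% of 2-fold and 89% of 4-fold changes, with 5 false among 106 calls. At hour 1 (3011 genes) it recovered 1% and 28%, with 2 false among 31 calls. In the comparison of periods (8992 genes) it recovered 0% and 2%, with 0 false among 2 calls, and DESeq2 (9255 genes) recovered 1% and 20% there. DESeq2 made 26 false calls among 145 over the summed hours. No library was left out of the main comparisons. Coordinates are not given, because the build of the counting is unknown.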

Results

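Read counts were available for 52 libraries from control flasks at 20 °C and 52 from heated flasks at 28 °C, with 4 libraries in each of 26 groups of arm and hour. The series title describes the heat stress as gradual, and the rate of warming is not given in the sources used here. Reads assigned to genes numbered 183957 to 617891 per library (median 371250), out of 6754840 to 13665600 listed reads. The assigned share had a median of 2.87% in control and 4.01% in heated libraries. A median of 89.4% of all listed reads was counted to no gene model. Under stranded counting that share would include reads on the other strand of a gene. A floor of 3 counts corresponds to 4.86 to 16.3 CPM per library, and such floors and intervals cover counting error only. Within groups, pairs of libraries differed by more than counting error, with a chi-square per degree of freedom of 2.63 to 28.3 over 156 pairs. The library kit marks strand and the strand setting of the counting is not given. It is therefore unknown whether the count of any gene named here holds reads from the strand of its transcript.

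The libraries fell into 2 sets that followed their file numbers, a split found after the data were seen. The first principal component, with 35.9% of the variance over 5115 genes, placed 58 libraries at -62.5 to -5.85 and 46 libraries at 8.93 to 63.1. On the second component the control libraries scored 9.27 to 28.3, and the 2 libraries with conflicting labels scored -36.6 and -39.7. Those scores argue against the control arm for these 2 libraries and do not decide their culture. The second set held 28 heated and 18 control libraries, among them every library of both flasks of culture 4 and of heated culture 3. At hours 1 to 7 it held 2 heated and 1 control library per hour, and control culture 3 belonged to the first set up to hour 8 and to the second from hour 9. In 4 libraries of the second set, each set against the nearest 1 or 2 hours of its flask that belonged to the first set, the 35 light harvesting genes were higher by a median of 1.97 (log2). HSP70A, a heat shock protein of the 70 kDa family by its symbol, had a median of 190 TMM-scaled CPM in the 34 control libraries of the first set and 1230 CPM in the 18 of the second set.

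**Figure D1:**
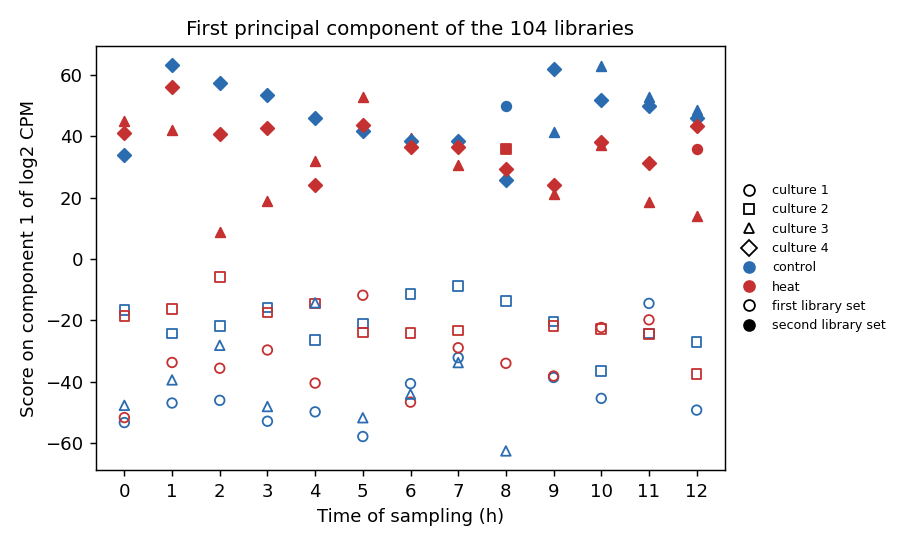
Score of each library on the first principal component of log2 CPM (vertical axis) against hour of sampling (horizontal axis), with the shape giving the culture, the colour the arm and the fill the library set. The 58 libraries of the first set lie between -62.5 and -5.85 and the 46 of the second between 8.93 and 63.1.

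The main comparison asked how 12 h of heat changed the transcripts of the cultures, with hours 1 to 12 summed per flask. Among genes named by the rule that have a symbol, the 3 largest rises were those of Tpt4, a plastid triose phosphate translocator by its symbol, and of HSP20C and HSP20A, small heat shock proteins that as chaperones bind unfolded proteins. Tpt4 (PHATRDRAFT_56463) rose from 24.2 ± 8.41 CPM in control flasks to 665 ± 98.7 CPM in heated flasks (SD, n = 4 each, log2 4.76, SE 0.339, adjusted p = 5.14e-05). HSP20B rose from 158 ± 44.7 to 900 ± 114 CPM (log2 2.51, adjusted p = 0.000434), HSP20A from 4.37 ± 1.64 to 107 ± 34.1 CPM (log2 4.61, adjusted p = 9.01e-05) and HSP20C from 2.11 ± 1.28 to 61.9 ± 40.4 CPM (log2 4.76, adjusted p = 0.000629). In the other direction, the linker histone gene H1, whose product binds DNA between nucleosomes, fell from 323 ± 71.9 to 58.9 ± 11.4 CPM (log2 -2.45, adjusted p = 0.000275). GOX, which encodes the photorespiratory enzyme glycolate oxidase, fell from 919 ± 187 to 328 ± 74.4 CPM (log2 -1.49, adjusted p = 0.00681).

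Further named genes, chosen by the rule for the same direction in all 4 culture pairs, were chlM of chlorophyll synthesis (magnesium protoporphyrin methyltransferase), from 34.3 ± 15.3 to 179 ± 55.2 CPM (log2 2.38), and FABG of fatty acid synthesis, from 42.7 ± 23.1 to 174 ± 85.6 CPM (log2 2.01). Tpt6, a further triose phosphate translocator by symbol, rose from 25.1 ± 6.87 to 82.7 ± 26.4 CPM (log2 1.71). The kinase gene hCDK6 rose by log2 3.44, HSP20 by 2.38 and CacyBP by 1.87. Among named genes that fell were HemE_2 of tetrapyrrole synthesis (uroporphyrinogen decarboxylase), from 5058 ± 1720 to 1855 ± 757 CPM (log2 -1.45), and L-SD (PHATRDRAFT_877, serine dehydratase), from 271 ± 39.1 to 93.8 ± 17.4 CPM (log2 -1.53). DHLTA_4, the acetyltransferase of the pyruvate dehydrogenase complex, fell by log2 -1.55, and its gene model overlaps a neighbouring model. ATPase2-1B, an ATPase by its symbol, fell by log2 -1.73. The adjusted p of these 10 genes with a symbol ranged from 0.000246 for hCDK6 to 0.0412 for HemE_2. Of genes without a symbol, PHATRDRAFT_38708 (log2 4.66) and PHATRDRAFT_34423 (4.01) rose, and PHATRDRAFT_37964 (-2.76) and PHATRDRAFT_13154 (-2.58) fell. Without heated flask 4 the change of PHATRDRAFT_34423 was 2.73, and without control flask 4 that of PHATRDRAFT_13154 was -1.21. In the 8 fits that each left out 1 flask, HemE_2 (log2 -1.67 to -1.28) and PHATRDRAFT_13154 (-2.94 to -1.21) lost the call in 6, CacyBP (1.62 to 2.27) in 3 and FABG (1.69 to 2.43) in 1, without control flask 3.

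In the test behind these values, 926 of 9820 genes were called, 684 higher and 242 lower in heated flasks. With the culture number as a replicate block the count was 3399, of which 925 were among the 926. With RLE size factors 63.2% of calls were higher, against 73.9% with TMM. Leaving out control flask 1 or 3 or heated flask 1 or 2 gave 617, 453, 541 and 542 called genes. Within the first library set (hours 1 to 7) and the second (hours 1, 2 and 4 to 7), Tpt4 differed by log2 6.26 and 4.84, the latter from 1 control flask, H1 by -3.7 and -3.42, and with the library set share as a covariate 3377 genes were called, again with 925 of the 926.

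All 4 small heat shock protein genes rose, both over all genes and adjusted over the list alone. The list lay above other genes by camera (adjusted p = 4.86e-12), also with an estimated correlation (adjusted p = 0.00686), and in the fit with the replicate block the latter adjusted p was 0.195. HSP20 was not called with limma-trend (log2 1.07), in the first library set (1.30) or on the first plate (2.58). Genes beside 3 of them rose as well: the neighbours of HSP20C by log2 3.46 and 2.76, those of HSP20B by 2.00 and 2.28, and 1 neighbour of HSP20 by 2.89. Whether reads were lost or misplaced between similar members of this family was not tested, so their single values are uncertain. Of the 7 HSP70 genes, which encode larger chaperones, 0 were called by edgeR over the summed hours and 0 adjusted over the list alone, with a median log2 of 0.15 (camera adjusted p = 0.685). The same holds for HSP90 (log2 0.19), for the 2 HSP40 genes (median log2 -0.11) and for the 3 heat shock transcription factor genes, with a median log2 of 0.64. The fit with the replicate block called 2 HSP70 and 2 heat shock transcription factor genes higher. Of the chaperonin genes CPN60_1 (log2 0.31) and CPN60_2 (log2 -1.29) neither was called, and CPN60_2 was lower adjusted over the list alone and in the fit with the replicate block (log2 -1.24, adjusted p = 0.000195). At an unadjusted p under 0.05, 2352 of all genes passed by edgeR, and DESeq2 called 1249.

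Core histone genes package DNA. Of 12, 6 fell, 0 rose and 6 were not called, and 10 were lower adjusted over the list alone. H3-1a fell from 101 ± 32.5 to 31.3 ± 6.94 CPM (log2 -1.68, adjusted p = 0.00399), H2A-3a by log2 -1.70 (adjusted p = 0.0384) and H2B-1a by -1.51 (adjusted p = 0.0198). The list lay below other genes by camera (adjusted p = 5.96e-08). With an estimated correlation the list had an adjusted p = 0.236, and 0.334 with the replicate block. H1 and H3-1a are neighbouring genes, and whether reads were lost or misplaced between similar histone copies was not tested, so single copies are uncertain. Without control flask 4 the change of H2A-3a was -1.25, and its call was lost in 5 of the 8 fits that each left out 1 flask. H2B-1a lost its call without control flask 3 (log2 -1.48) and without heated flask 1 (-1.31). In the blocked fit 11 of the 12 were called lower.

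Of 7 DNA replication genes, MCM2 rose from 21.7 ± 8.68 to 66.5 ± 12.8 CPM (log2 1.60, adjusted p = 0.00767) and MCM4 from 38.5 ± 3.48 to 78.6 ± 11.0 CPM (log2 1.03, adjusted p = 0.0152), both subunits of the replicative helicase. MCM4 lost its call without control flask 1 or 3 (log2 0.98 each) and without heated flask 2 (0.95). The other 5 passed neither over all genes nor adjusted over the list alone, and the list had a camera adjusted p = 0.708. In the blocked fit MCM6 was called lower (log2 -0.59, adjusted p = 0.013), and 2 genes were lower adjusted over the list alone. The median log2 of the list was -0.22 while its mean was 0.13 and camera placed it upward. Of 27 tested cyclin and cell cycle kinase genes 0 were called by edgeR (0 also adjusted over the list alone, camera adjusted p = 0.685), with a median log2 of 0.06, a mean of 0.01 and a downward sign in camera. The blocked fit called 2 of these genes higher and 4 lower. The kinase gene hCDK6, called higher as given above, was not matched to this list by its symbol.

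Light harvesting genes, whose products bind the pigments of the antenna, mostly did not pass the test. Of 34 tested, 2 rose and 0 fell, 1 of them also adjusted over the list alone (camera adjusted p = 0.708). Lhcf15 rose from 24.2 ± 4.37 to 78.2 ± 50.3 CPM (log2 1.70, adjusted p = 0.0189) and Lhcr10 by log2 1.63 (adjusted p = 0.0403), the latter in 3 of 4 pairs. Lhcr10 lost its call in 5 of the 8 fits that left out 1 flask (log2 1.34 to 1.87), and Lhcf15 in 1, without control flask 3 (1.70). Without heated flask 4 the change of Lhcf15 was 1.16, and with the replicate block 8 light harvesting genes were called higher and 5 lower. This list differed between the library sets, as given above, and reads lost or misplaced between similar members were not tested. Of 5 genes matched to photosystems and electron transport, 0 were called by edgeR, and 1 was lower adjusted over the list alone (camera adjusted p = 0.282). With the replicate block 2 were called lower, PsbO of photosystem II (log2 -0.52, adjusted p = 0.0047) and PSAT (-0.83, adjusted p = 0.00317). PSAT is phosphoserine aminotransferase, matched by its symbol only.

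Of 4 ribosomal protein genes, rps19 fell by log2 -1.56 (adjusted p = 0.0471) and 3 were lower adjusted over the list alone. The call of rps19 was lost in 5 of the 8 fits that left out 1 flask (log2 -1.96 to -1.07). The values of rpl2 (log2 -1.59, adjusted p = 0.107), rpl14 (-1.12, adjusted p = 0.134) and rpl20 (0.33, adjusted p = 0.735) did not pass, and with the replicate block rpl2 (-1.52, adjusted p = 6.1e-06) and rpl14 (-1.08, adjusted p = 0.000189) did. Without control flask 4 rpl2 was at -0.94, rpl14 at -0.64 and rpl20 at 0.95. The list had a camera adjusted p = 0.088, which was 0.0012 with the replicate block and 0.019 to 0.286 without 1 flask, under 0.05 without control flask 1 or 2 or heated flask 4. With an estimated correlation the adjusted p was 0.626, and 0.365 with the block. CHLH of chlorophyll synthesis (log2 -0.33), Sec61alpha of the translocon (-0.33), the alternative oxidase gene AOX1 (-0.06) and RNAse-H (-0.47), each the only match of its list, were not called, nor adjusted over the list alone. With the replicate block CHLH (-0.36, adjusted p = 0.0442) and Sec61alpha (-0.34, adjusted p = 0.00979) were called lower.

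**Figure D2:**
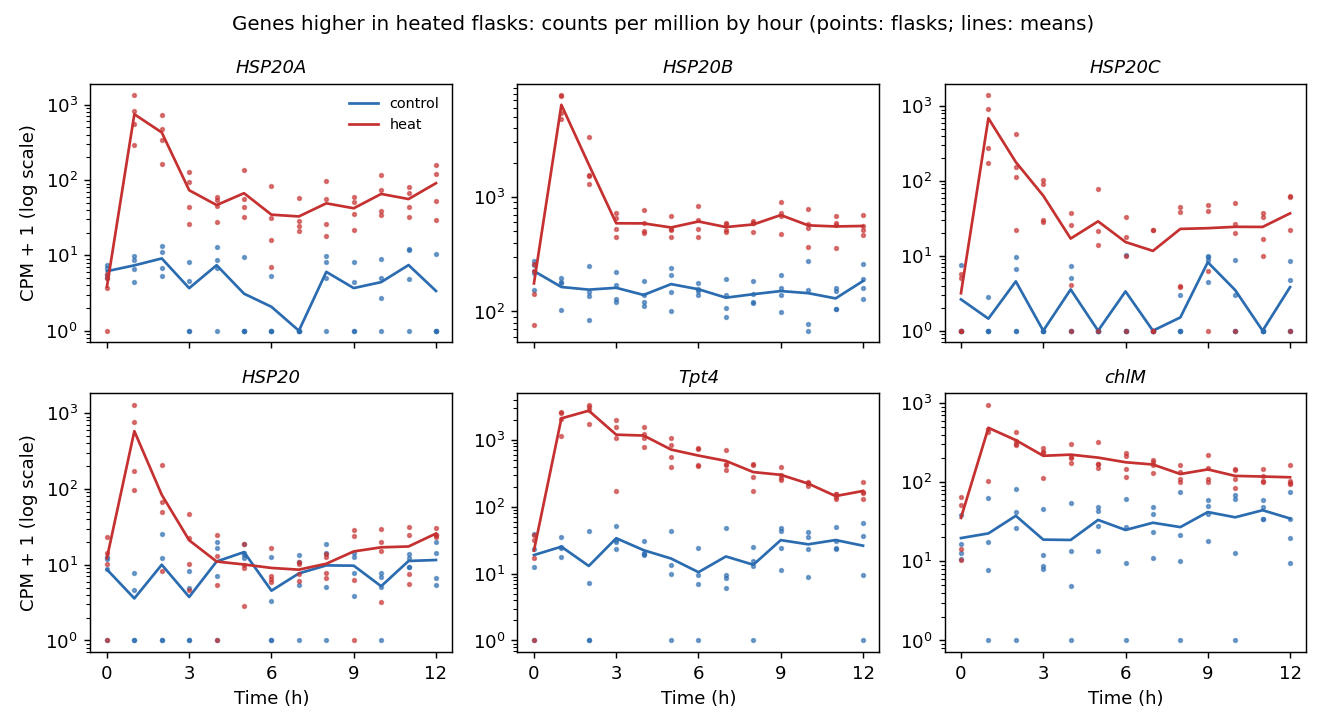
TMM-scaled CPM plus 1 on a log scale (vertical axis) against hour (horizontal axis) for 6 genes that were higher in heated flasks over the summed hours, with points for the 4 flasks per arm and lines for their means. HSP20B had a mean of 6390 CPM in heated libraries at hour 1 and 558 CPM at hour 12, against 163 and 184 CPM in control libraries.

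At hour 0, the first sampling point, the arms were compared at the start of the series. Tpt4 had means of 18 and 21.2 TMM-scaled CPM in control and heated libraries, and H1 had means of 303 and 276 CPM. Of 3443 genes edgeR called 0, with 60 at an unadjusted p under 0.05, and DESeq2 also called 0.

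At hour 1 small heat shock protein genes stood at their highest. HSP20B rose from 151 ± 19.2 to 4602 ± 873 CPM (SD, n = 4, log2 5.42, SE 0.29, adjusted p = 1.17e-05), Tpt4 by log2 6.41 (adjusted p = 7.47e-05) and FABG by 5.66 (adjusted p = 0.00297). HSP20C had 1 count in the 4 control libraries and 853 in the heated ones, a ratio of 817 with a 95% counting interval of 146 to 32300 (adjusted p = 0.000607). HSP20A rose by log2 6.82 and HSP20 by 7.57, the latter from 4 control counts. Without control library 4 the change of FABG was 6.74, and without heated library 3 that of HSP20 was 6.87. For HSP20C the fit without control library 4 gave 10.63, but against 0 control counts, so the size of that value is not measured. The larger chaperone genes HSP90 (log2 2.68, adjusted p = 0.0218), Hsp70_1 (2.49, adjusted p = 0.0359), HSP70F (2.53, adjusted p = 0.0487) and HSP70G (1.79, adjusted p = 0.0308) rose at this hour, as did the transcription factor gene HSF3 (2.8, adjusted p = 0.0417). These 5 genes lie outside the naming rule and were chosen after their values were seen. At this hour more heated than control libraries belonged to the second library set, in which HSP70A was higher among control libraries. The sizes of the HSP70 and HSP90 rises are therefore not separate from the library sets. At hour 0, with the same flasks in the second set, edgeR called 0 of 3443 genes. The set makeup alone gave no calls at that hour.

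Genes that fell most at hour 1 included ISIP1, an iron starvation induced protein, from 384 ± 134 to 36.2 ± 27.3 CPM (log2 -3.02, adjusted p = 0.00286). SMC, of chromosome structure, fell by log2 -2.94 (adjusted p = 0.00434), the meiotic mismatch repair homologue MSH5 by -2.91 (adjusted p = 0.00145), ATPase2-1B by -2.79 (adjusted p = 0.00137) and TPS2 by -2.48 (adjusted p = 0.0126), or by -3.23 without heated library 4. Over the summed hours ISIP1, SMC, MSH5 and TPS2 were not called, with adjusted p of 0.746, 0.154, 0.773 and 0.835, and with the replicate block SMC was (log2 -0.72, adjusted p = 0.00156).

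At hour 1, 922 of 3206 tested genes were called, 474 higher and 448 lower. All 4 small heat shock protein genes rose, also adjusted over the list alone (camera adjusted p = 1.76e-08). With an estimated correlation that list had an adjusted p = 0.0864. Of the 7 HSP70 genes 3 rose, and 6 adjusted over the list alone, with a camera adjusted p = 0.106. Of 7 histone genes tested 0 were called by edgeR, where 1328 of all genes passed at an unadjusted p under 0.05, and the list had a camera adjusted p = 0.352. The 7 were lower without a call, with a median log2 of -1.12. Without control library 1, 2 or 3 or heated library 1 or 3 the count of called genes was 471, 425, 451, 613 and 541, and 1 fit of all libraries called 1597.

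**Figure D3:**
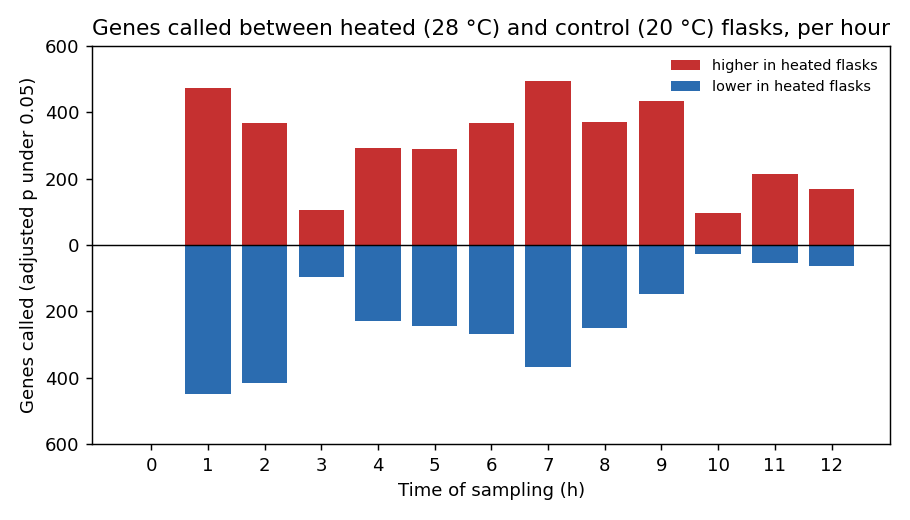
Number of genes called between heated and control libraries (vertical axis, higher above and lower below the zero line) at each hour of sampling (horizontal axis), by edgeR at an adjusted p under 0.05. The bars stand at 474 higher and 448 lower genes at hour 1, at 494 and 366 at hour 7 and at 0 at hour 0.

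The number of hours with a call differed between genes, and it does not measure how long a change lasted. HSP20A had a higher mean in heated than in control libraries at every hour from 1 to 12, such as 45.6 and 6.41 TMM-scaled CPM at hour 4. Genes with too few counts at an hour were not tested there. HSP20B was called higher at 12 hours, Tpt4 at 11, chlM at 9, hCDK6 at 7 and HSP20A at 6. The onset of chlM lay at hour 1, that of hCDK6 at hour 3 and that of Tpt6 at hour 11. H1 was called lower at 11 hours from an onset at hour 1, DHLTA_4 at 11 and L-SD and ATPase2-1B at 9 from hour 1, and GOX at 11 from hour 2. HemE_2 was called lower at 8 hours from hour 2 on. Mean TMM-scaled CPM of H1 in heated libraries was 3.84 ± 5.09 at hour 2, 64.3 ± 26.6 at hour 8 and 99.8 ± 34.8 at hour 12.

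**Figure D4:**
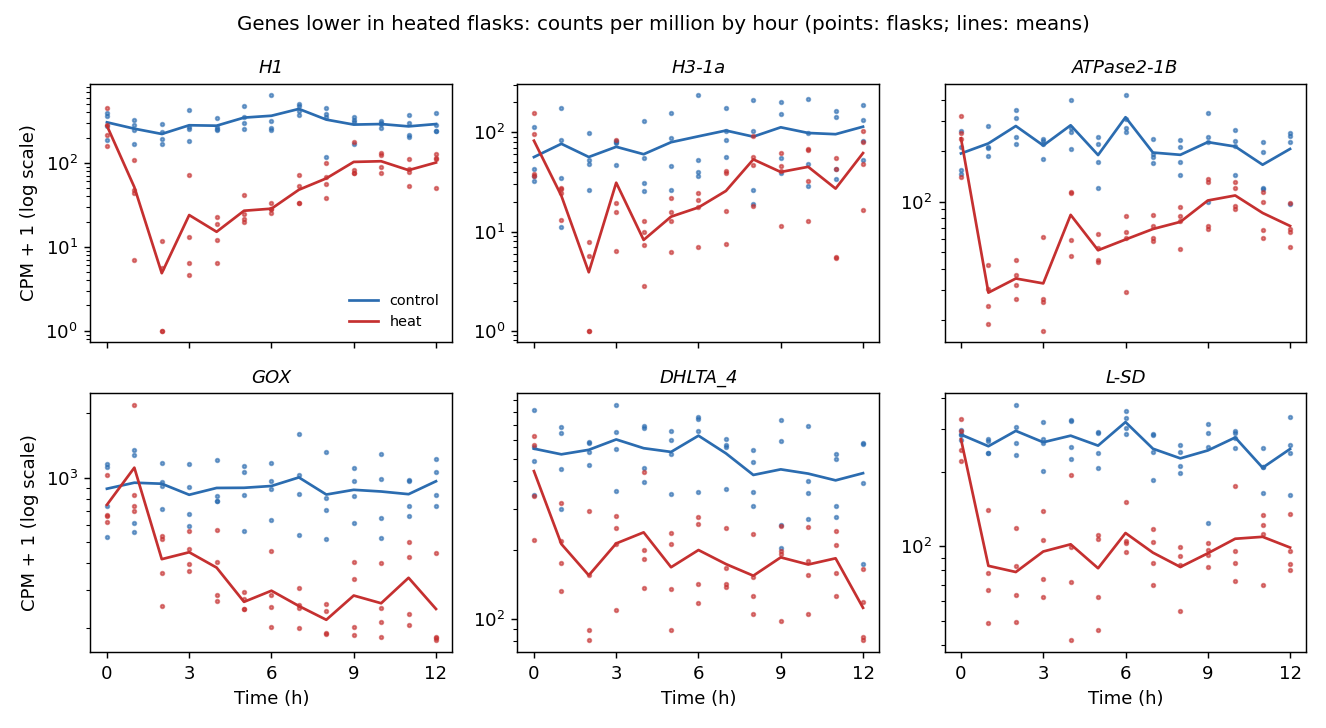
TMM-scaled CPM plus 1 on a log scale (vertical axis) against hour (horizontal axis) for 6 genes that were lower in heated flasks over the summed hours, with points for the 4 flasks per arm and lines for their means. H1 had a mean of 3.84 CPM in heated libraries at hour 2 and 220 CPM in control libraries.

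The number of called genes was 785 of 3406 at hour 2, 200 of 3652 at hour 3, 522 of 4124 at hour 4 and 534 of 4213 at hour 5. It was 634 of 4031 at hour 6, 860 of 4241 at hour 7, 622 of 4876 at hour 8 and 580 of 4714 at hour 9. It was 122 of 5301 at hour 10 and 270 of 5284 at hour 11. With the replicate block the counts were 1185 at hour 2, 349 at hour 3, 154 at hour 8, 1467 at hour 9, 809 at hour 10 and 967 at hour 11. At hour 9 the share of higher calls was 74.7% with TMM and 64.0% with RLE, and RLE moved the median of all genes by -0.14.

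Leaving out 1 library moved these counts by over 1.5 times in the following fits. The count at hour 2 was 421, 399 and 436 without control library 1, 2 or 3, and 392 and 451 without heated library 2 or 3. Hour 3 gave 38, 17, 35 and 423 without control library 1, 2, 3 or 4, and 16, 34, 58 and 456 without heated library 1, 2, 3 or 4. Hour 4 gave 311, 210 and 265 without control library 1, 2 or 3, and 296, 215 and 278 without heated library 1, 2 or 4. Hour 5 gave 173, 140, 156 and 888 without control library 1, 2, 3 or 4, and 225, 283 and 294 without heated library 1, 2 or 4. Hour 6 gave 351, 261 and 298 without control library 1, 2 or 3, and 343, 364 and 417 without heated library 1, 2 or 4. Hour 7 gave 518 and 550 without control library 2 or 3. Hour 8 gave 342 and 409 without control library 2 or 4, and 395, 281 and 337 without heated library 2, 3 or 4. Hour 9 gave 350 without control library 2, and 285, 240, 320 and 325 without heated library 1, 2, 3 or 4. Hour 10 gave 39, 75 and 16 without control library 2, 3 or 4, and 19, 18 and 27 without heated library 1, 2 or 3. Hour 11 gave 112 and 108 without control library 3 or 4, and 97, 68 and 89 without heated library 1, 2 or 3.

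At hour 4 the 24 tested light harvesting genes had a median log2 of 0.88, with 0 called by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.884 with an estimated correlation). At that hour 2 heated and 1 control library belonged to the second set, in which these genes were higher. Histone genes at that hour had a camera adjusted p = 0.049, with 1 of 5 called lower, 2 adjusted over the list alone, and an adjusted p = 0.585 with an estimated correlation. At hour 8, 0 of 12 histone genes were called by edgeR, where 1310 of all genes passed at an unadjusted p under 0.05, and 11 of the 12 had a negative log2 (median -0.89).

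At hour 12 the small heat shock protein genes HSP20A and HSP20B were still higher, and besides HSP20A the rule named Tpt6, VDE, myoC1 and Lhcf15 as higher. Other named genes also had higher means, such as Tpt4 with 171 TMM-scaled CPM in heated and 25.2 in control libraries, and chlM with 114 and 33.8. HSP20A had 2 counts in the 4 control libraries and 259 in the heated ones, a ratio of 82.9 with a 95% counting interval of 22.7 to 688 (adjusted p = 0.0172). Tpt6 rose from 22.4 ± 18.3 to 177 ± 69.0 CPM (SD, n = 4, log2 2.73, adjusted p = 0.0172). VDE, the violaxanthin de-epoxidase of the xanthophyll cycle, rose from 18.8 ± 6.46 to 92.1 ± 13.3 CPM (log2 2.11, adjusted p = 0.0154). The myosin gene myoC1 rose by log2 3.4 (adjusted p = 0.00583) and Lhcf15 by 3.29 (adjusted p = 0.0283). GOX fell from 949 ± 71.9 to 299 ± 217 CPM (log2 -1.90, adjusted p = 0.0233), DHLTA_4 by log2 -1.88, ATPase2-1B by -1.51, H1 by -1.47 and L-SD by -1.27, the last with an adjusted p = 0.0486.

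At hour 12, 233 of 5545 genes were called, 170 higher and 63 lower, and 148 with the replicate block. In the blocked fit the change of Lhcf15 was 2.90, of H1 -1.53, of ATPase2-1B -1.45 and of L-SD -1.29, and none of these 4 was called. Of 12 histone genes, all with a negative log2 (median -0.68), 0 were called by edgeR and 0 adjusted over the list alone (camera adjusted p = 0.0942), with 1081 of all genes at an unadjusted p under 0.05 and 480 called by DESeq2. Without control library 1, 2 or 4 or heated library 1 or 3 the count was 87, 84, 92, 78 and 28, and without heated library 2, whose labels conflict, it was 112. In the 8 fits that each left out 1 library, GOX, DHLTA_4 and L-SD lost their calls in 6 and ATPase2-1B and H1 in 7. Of the genes that were higher, Lhcf15 (log2 2.24 to 3.57) and VDE (1.96 to 2.34) lost theirs in 5, and Tpt6 (2.49 to 3.26) and HSP20A (5.24 to 8.71) in 3. The 8.71 came without control library 2, the only control library with counts of HSP20A at that hour, so its size is not measured.

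The test of whether the heat effect itself differed between hours 1 to 4 and hours 9 to 12 called few genes. Its main fit took the early and late sums of a flask as independent. The heat effect on Tpt4 was smaller in the late period by log2 -3.27 (SE 0.44, adjusted p = 0.00297), although Tpt4 was also higher at 11 single hours. PHATRDRAFT_17362 changed likewise by -3.71 (SE 0.48, adjusted p = 0.00297) and PHATRDRAFT_46490 in the other direction by 3.58 (SE 0.52, adjusted p = 0.00634). The latter 2 have no symbol and were chosen after their values were seen. Tpt4 lost its call without control culture 3 or heated culture 1 (range -3.43 to -3.07 over the 8 fits that left out 1 flask), and PHATRDRAFT_46490 in 4 of those 8 fits (3.28 to 4.25). Small heat shock protein genes had a median difference of -2.35, with 0 of 4 called by edgeR and 3 lower adjusted over the list alone. As a list they lay below other genes by camera (adjusted p = 7.09e-06), also with an estimated correlation (adjusted p = 0.0149). HSP70 genes (median -1.24, camera adjusted p = 0.0126) and light harvesting genes (median -1.16, camera adjusted p = 4.2e-05) lost that call with an estimated correlation (adjusted p = 0.331 and 0.484). Control culture 3 was in the first library set at hours 1 to 4 and in the second at hours 9 to 12, and light harvesting genes and HSP70A were higher in the second, so these list values are not separate from the library sets. With the set share as a covariate 361 genes were called in this comparison. In these lists 0 genes were called by edgeR.

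Of 9255 genes in that test 3 were called by edgeR, with 721 at an unadjusted p under 0.05. DESeq2 called 89, and the fit with each flask as a block, which pairs its early and late sums, called 149. Without heated culture 4 the count was 29, without hour 3 it was 42, without control culture 4 it was 7, and without control culture 3 or heated culture 1 it was 1.

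The control flasks alone were compared over the same periods, to look for drift without heat. Tpt4 had means of 24.3 TMM-scaled CPM at hour 1 and 25.2 at hour 12 in control libraries, and H1 had means of 254 and 289 CPM. Of 7241 genes edgeR called 0, with 33 at an unadjusted p under 0.05, and DESeq2 called 0. The edgeR fit took early and late sums of a flask as independent, and a control culture changed library set between the periods. Regrouping these sums gave up to 2098 called genes, so variation other than period was large. With the replicate block or the set share as a covariate 0 were called, with 190 and 140 at an unadjusted p under 0.05. The absence of calls therefore does not show that drift was absent.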

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

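Of the tests below, those of the ambiguous share, of light harvesting genes between the library sets and of regrouped samples were written down before their values were seen, and the others were chosen only after the result was seen.

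In control libraries the 35 light harvesting genes, known as abundant transcripts of diatoms in the light, had a median percentile of 83.4 by mean CPM (highest 91.6). Over all libraries a median of 89.4% of reads was counted to no gene model. That low percentile of 83.4 was itself the observation that raised the question, and a rank near the top is an assumption, so it decides neither for nor against any of the explanations below. The ambiguous share was 0.777 times the share of overlapping gene length, a value that counting without regard to strand could give. The overlap was measured without the strands of the models. Models that overlap on the same strand would give such a value under stranded counting too. It therefore does not decide, and only 0.102% of gene length overlapped. Counting without regard to strand removes no reads from genes and so would not by itself account for few assigned reads. Counting on the strand opposite to the transcripts and loss of reads to rRNA or other sequence outside genes stay open, because the strand setting is not given and no value in hand decides. Low light harvesting transcripts in strong continuous light were not tested, and if the opposite strand was counted, the folds in the report describe antisense or leaked reads.

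The 2 library sets were weighed with 4 libraries of the second set, each against the nearest 1 or 2 hours of its flask that belonged to the first. Cultures that differ in biology are argued against, because those libraries moved by at least 79.1% of the gap between the sets. Deeper sequencing alone is argued against, because their share of assigned reads was higher by at least 24%. A larger share of reads from the transcript strand in the second set may be the cause, as light harvesting genes were higher there by a median log2 of 1.97, where random gene lists had a median of -0.05, but only if the counting kept strands apart, which the ambiguous share of 0.777 leaves open. As 28 of its 46 libraries were heated, the set partly follows the arm, and with the set share as a covariate 3377 genes were called over the summed hours, 925 of them among the 926.

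The heated library of culture 4 at hour 3 had 241 CPM of Tpt4, against 958 to 1760 CPM in the other heated libraries of that hour and 3540 and 1740 CPM in its own flask at hours 2 and 4. On an axis from hour 3 (0) to hours 10 to 12 (1) it scored 0.859, and the library set alone is argued against because hours 2 and 4 of the same flask and set scored 0.158 and 0.406. A library of a late hour under an early label may be the cause, with 0.859 inside the 0.841 to 0.871 of that flask at hours 10 to 12. These 4 libraries also have consecutive file numbers and 14.6 to 16.3% of reads aligned to more than 1 place, against 9.38% at hour 9 (score 0.981), so a batch shared by the 4 stays open as a source of their likeness. A short change in that flask at hour 3 alone was not tested.

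At hour 3, 200 genes were called with all 8 libraries, 456 without that library and 423 without control library 4.

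Among 114 groups of 4 values, 14 held a value far from the other 3, where chance gives about 1 in 20 independent groups. These groups share flasks and genes, so that share is only a rough yardstick. Most of the 14 came from culture 4, whose flasks lay wholly in the second library set, and whether the set gave rise to them was not tested. Of the 14, 2 (HSP20C and HSP20A) rest on 1 and 2 counts against 0 and show nothing beyond counting error. H1 stood at 429 CPM in control culture 2 (others 277 to 302) and at 75.9 CPM in heated culture 2 (others 51.6 to 55.2). L-SD stood at 120 CPM in heated culture 4 (others 84.6 to 85.6) and PHATRDRAFT_34423 at 289 CPM (others 25.2 to 54.3). In control culture 4, PHATRDRAFT_13154 stood at 389 CPM (others 22.0 to 75.9), Lhcf15 at 17.6 CPM (others 26.2 to 26.7) and TPS2 at 132 CPM (others 261 to 277). At hour 1 the same control culture had 2.16 CPM of HSP20C (others 0, floor of 3 counts 6.48 CPM), 112 CPM of FABG (others 18.9 to 23.9) and 160 CPM of MSH5 (others 318 to 328). At hour 12 HSP20A stood at 8.56 CPM in control culture 2 (others 0, floor of 3 counts 12.8 CPM). Heated culture 4 at hour 12 had 204 CPM of myoC1 (others 85.5 to 105), 527 CPM of Lhcf15 (others 79.3 to 96.2) and 624 CPM of GOX (others 164 to 219). In that library 16.3% of reads aligned to more than 1 place.

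The heat effect of hours 9 to 12 differed from that of hours 1 to 4 by log2 -3.71 in PHATRDRAFT_17362, 3.58 in PHATRDRAFT_46490 and -3.27 in Tpt4.

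Reads aligned to more than 1 place made up 10.1 ± 2.6% in heated flasks at hours 9 to 12 and 7.08 ± 0.26% in control flasks (n = 4 each, exact permutation p = 0.0286 with flasks taken as unpaired). Heated flasks were higher in 4 of 4 culture pairs, and the exact paired permutation p was 0.125, the smallest that 4 pairs allow. Without culture 4 the heated mean was 8.81%, and these reads were not given to genes.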

How the results depend on the processing

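Each result was run again under the alternatives, and those on library sets and without hour 3 were chosen only after the result was seen; the cause of a change was not tested. Over the summed hours the main count of 926 became 3399 with the replicate block, 3377 with the library set share as a covariate, 2584 with both and 1702 in the first library set at hours 1 to 7. Other counts over the summed hours stayed within 1.5-fold of 926, such as 823 with RLE size factors, 1249 with DESeq2 and 1147 with limma-trend. Leaving out 1 flask gave 453 to 974 called genes.

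Without the low-count filter the counts were 443, 91, 272, 244 and 377 at hours 2 to 6, 363 at hour 9 and 144 at hour 12. The replicate block gave 1185 at hour 2, 349 at hour 3, 154 at hour 8, 1467 at hour 9, 809 at hour 10, 967 at hour 11 and 148 at hour 12. DESeq2 gave 342 at hour 3, 324 at hour 10, 461 at hour 11 and 480 at hour 12. One fit of all libraries gave 1597 at hour 1, 462 at hour 3, 485 at hour 10 and 557 at hour 12. The first plate only gave 456 at hour 3, 417 at hour 6 and 275 at hour 9. Without the library with conflicting labels 68 genes were called at hour 11 and 112 at hour 12.

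The library set as a term gave 379, 833, 912, 1099, 1445 and 1191 called genes at hours 3 to 8, and 1238, 868, 969 and 746 at hours 9 to 12. With the block added the counts were 2 at hour 0, 1087 at hour 6, 1145 at hour 8 and 674 at hour 12, and this fit was not possible at hours 9 to 11.

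Leaving out 1 library gave 0 to 0 called genes at hour 0, 425 to 1273 at hour 1, 392 to 1099 at hour 2, 16 to 456 at hour 3 and 210 to 681 at hour 4. The ranges were 140 to 888 at hour 5, 261 to 735 at hour 6, 518 to 1025 at hour 7, 281 to 765 at hour 8 and 240 to 572 at hour 9. They were 16 to 140 at hour 10, 68 to 403 at hour 11 and 28 to 287 at hour 12.

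In the comparison of periods the main count of 3 became 89 with DESeq2, 149 with each flask as a block and 88 with limma-trend. It became 10 with hours 9 and 10 as the late period, 42 without hour 3 and 361 with the library set share. Leaving out 1 flask gave 1 to 29 there, and 0 to 0 for drift in control flasks.

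Among named genes only TPS2, not called over the summed hours at log2 0.15, changed its sign: -0.05 without control flask 4, -0.05 on the first plate, -0.07 in the first library set and 0 with limma-trend. Leaving out 1 flask gave TPS2 -0.05 to 0.29. HSP20 had log2 1.30 in the first library set and 1.07 with limma-trend, and was not called there.

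Lists that changed sign were not called. With fry, a directional test and not a competitive one, ER and periplastid degradation, fatty acid, proteasome and tetrapyrrole enzyme lists had adjusted p = 0.913. With the replicate block the ER and periplastid list had adjusted p = 0.978 and the fatty acid list 0.902. With the set share, kinesins and myosins had 0.478 and light harvesting genes 0.635. Leaving out 1 flask gave adjusted p of 0.58 to 0.961 for kinesins and myosins, 0.137 to 0.896 for light harvesting genes, 0.813 to 0.961 for mitotic checkpoint genes, 0.534 to 0.961 for DNA repair and for proteasome genes, 0.663 to 0.992 for the ER and periplastid list, 0.523 to 0.961 for fatty acid genes and 0.555 to 0.961 for tetrapyrrole enzymes. With the replicate block fry called the lists of glycine, serine and photorespiration enzymes (adjusted p = 0.0439), of ATPases (0.0299) and of ribosomal proteins (0.0103). Apart from calls given here or beside results, the block changed no other call of a named gene or fixed list in the comparisons it was tried on.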

Other observations

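Genes and lists in this part lie outside the naming rule and were chosen only after the result was seen, while the test of regrouped samples was fixed before. In the list of 17 plastid envelope transport genes, Tpt4, Tpt6, NTT2 (log2 1.17, adjusted p = 0.0129), NTT6 (1.29, adjusted p = 0.0163) and Tic55 (1.33, adjusted p = 0.0459) rose over the summed hours. Adjusted over the list alone 5 rose and 2 fell, and camera gave an adjusted p = 0.52. The median log2 of that list was -0.04 and its mean 0.36. Anaphase promoting complex genes APC7 (log2 1.71, adjusted p = 0.00173) and APC8 (1.48, adjusted p = 0.00711) rose, in a list of 20 with a camera adjusted p = 0.851. In 16 genes of glycine, serine and photorespiration enzymes, GOX and L-SD fell (camera adjusted p = 0.354), and 3 were lower adjusted over the list alone.

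Of 18 chaperone genes together 4 rose, all of them small heat shock proteins, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0308). With an estimated correlation the adjusted p was 0.947, and without control flask 1 or 2 or heated flask 3 or 4 the camera adjusted p was 0.2, 0.107, 0.263 and 0.101. At hour 1, 9 of 15 rose and 12 adjusted over the list alone (camera adjusted p = 6.21e-06), with an adjusted p = 0.683 with an estimated correlation. For the 13 other lists made from symbols, among them vesicle trafficking, DNA repair and antioxidant genes, the camera adjusted p was 0.52 to 0.897 over the summed hours.

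In the comparison of hours 9 to 12 with hours 1 to 4, 5 of the lists made from symbols lay below other genes by camera. These were chaperones together (median -1.40, adjusted p = 4.76e-06), fatty acid enzymes (-0.75, adjusted p = 0.000473), tetrapyrrole enzymes (-1.02, adjusted p = 0.0051), ER and periplastid degradation (-0.64, adjusted p = 0.0051) and plastid envelope transport (-0.26, adjusted p = 0.00517). With an estimated correlation their adjusted p was 0.283, 0.411, 0.329, 0.411 and 0.0869. Tpt4 was the 1 called gene in these lists, and adjusted over the list alone 4 chaperone, 1 fatty acid and 2 plastid envelope transport genes were lower. These values too come with control culture 3 in the first library set early and in the second late. By fry, a directional test, plastid envelope transport had an adjusted p = 0.0471.

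The 8 samples of each comparison were also regrouped in all 35 ways. The real grouping gave the most called genes at hour 1 (922, highest other 115), hour 2 (785 and 131), hour 3 (200 and 0), hour 4 (522 and 190) and hour 5 (534 and 417). The same held at hour 6 (634 and 365), hour 7 (860 and 193), hour 8 (622 and 0), hour 12 (233 and 1) and for the comparison of periods (3 and 0), where 1 of 35 groupings, the real one, reached the count. For the summed hours (926), hours 9 (580), 10 (122) and 11 (270) 2 of 35 reached it, and the grouping of cultures 1 and 2 against 3 and 4 gave 2399, 596, 1505 and 464. That grouping follows the library sets at hours 9 to 11. Over the summed hours it follows them only in part, because control culture 3 was in the first set up to hour 8. These 35 ignore the pairing by culture, and among the 8 groupings that part the flasks of every culture the highest count besides the real one was 0 for each of these 4 results, although 8 are too few for a share under 0.05. At hour 0 and for drift in control flasks, with 0 called, 35 of 35 reached it and the highest others were 429 and 2098.

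Of 893 genes called at hour 1 and tested at hour 12, 67 (7.5%) were called there in the same direction and 8 in the opposite one, and 619 had the same sign. Of the genes tested at both hours 156 were called at hour 12. The 67 were 40 higher and 27 lower genes, where independent lists would share 13.2 and 8.78. Both hours come from the same flasks, so that is no fair null value. In the test of the difference itself Tpt4 was 1 of 3 called genes.

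Adjacent genes called in the same direction over the summed hours formed 84 pairs. In 10000 random placements the mean was 51.8 and the highest count 82 (one-sided permutation p = 1e-04, the smallest that 10000 placements give). The small heat shock protein genes HSP20B and HSP20C, with neighbours that rose, and the pair of H1 and H3-1a are examples.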
